A study of Mus musculus with 12 samples.

How the data were processed

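RNA was measured in 12 libraries of naive CD8 T cells from spleens of 6-week-old mice on the C57Bl/6 background. Per the labels, naive cells low in CD44 were sorted from wild-type animals or from animals homozygous for the Ikaros-Zn4 mutation, and were harvested directly or after 12 h or 24 h on plates coated with antibodies against CD3 and CD28. This gives 2 genotypes at 3 times, 6 groups with 2 libraries each. The labels do not say whether replicates are separate animals. The libraries were stranded, single-end mRNA libraries read on an Illumina HiSeq instrument.

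The authors aligned the reads with TopHat2 2.0.12 and assigned them to genes with HTSeq 0.6.1, per the submitters' processing notes, which give the genome as mm10 and GRCm38. The deposited table holds RPKM values (reads scaled by gene length and by the library's total reads) for 12892 lines and 12885 gene symbols; 7 symbols occur on 2 lines and the line listed before the other was kept. The lowest value of a gene's highest group mean is 1.0005 RPKM, so genes below 1 RPKM in every group are absent from the table. Within a library the values are whole multiples of a step, and whole reads were worked out for 12794 genes (99.3%; tolerance 0.02 reads). The gene lengths implied by these steps equal the summed exon length in the GENCODE M21 annotation of GRCm38 for 7080 of 12146 genes (58.3%; tolerance 0.5 bp). The library totals recovered in this way run from 24263907 to 33389808 reads, with 73.8% to 76.3% of reads in listed genes at 0 h and 82.4% to 86.0% after stimulation. At these depths, 3 reads in a gene of 2 kb correspond to 0.0449 to 0.0618 RPKM.

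Values were analysed as log2(RPKM + 1), a choice that damps the change of any gene near or below 1 RPKM in a group, so that its log2 change is not a ratio of levels. Genes with at least 1 RPKM in at least 2 libraries were tested (12726 genes). A single limma model (limma 3.58.1, R 4.3.3; empirical Bayes with a mean-variance trend) with a mean per group was fitted to all 12 libraries, which leaves 6 residual degrees of freedom, and 11 comparisons were drawn from it: each pair of times within a genotype, Zn4 against WT at each time, and the difference in response between genotypes at 12 h and 24 h (the genotype by time interaction). Changes are given with the standard error of the model, and levels as group means with the SD of 2 libraries. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes under 0.05 were called. The deposited scaling was kept; no other scaling was applied outside the alternatives.

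Groups of genes were tested with camera from limma at a preset correlation between genes of 0.01, and again with an estimated correlation. The 26 lists, of which 24 had at least 3 tested members, cover T cell activation, cytotoxic genes, cytokines and chemokines, naive-state genes, inhibitory receptors, Ikaros and NuRD genes, G1/S, G2/M, glycolysis, ribosome biogenesis, amino acid and one-carbon metabolism, sterol and lipid synthesis, interferon-stimulated genes, T cell receptor signalling, STAT5 targets, Notch targets, other T cell lineages, memory, trafficking, survival and p53 targets, cell stress, and markers of progenitors, B cells, myeloid cells, natural killer and gamma-delta T cells, and erythroid cells. Camera p-values were adjusted over the lists within a comparison. Some genes belong to more than 1 list, so calls of different lists are not independent. Members called are counted after adjustment over all tested genes, and also after adjustment over the list alone. The genes that WT cells induce or repress at least 2-fold at 1 time were tested as classes at the other time, so that no WT library of that time defines the class.

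The comparisons, the tests, the thresholds, the lists and the main alternatives were chosen before the data were examined. Genes are named by a rule: the 10 largest rises and 10 largest falls among called genes of a comparison, the 4 called genes with the largest change in each list, and 23 genes of T cell function and the Ikaros family; exceptions are named as such, and some genes that the rule selects are not reported here. The overlap of lists between comparisons that share no library is given with the number that independent lists of the same sizes would share.

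Alternatives were a pseudocount of 0.1, no filter, a filter at 5 RPKM, quantile normalization, median-ratio scaling, robust empirical Bayes, fits of only the libraries of a comparison, the replicate number as a block (shared or within genotype), a minimum change of 2-fold, camera with an estimated correlation, and leaving out each library in turn. A limma-voom fit to the recovered reads, a replicate block at each time point and a covariate for the summed level of 4 Y-linked genes were added later.

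The fit was tested on simulated data built from the recovered reads, with 200 changed genes and a replicate SD of 0.2 on the log2 scale. In Zn4 against WT at 24 h it recovered 2.86%, 61.4% and 96.5% of genes changed 1.5-fold, 2-fold and 4-fold, with 5.56% of calls false. At 12 h the shares were 1.64%, 54.2% and 95.1% (7.48% false), and at 0 h 6.45%, 59.0% and 86.8% (13.7% false). All simulated libraries had the same independent spread. In the real libraries the SD of the log2 difference between replicates was 0.346 and 0.324 at 0 h and 0.173 in WT at 24 h. Deviations of same-numbered libraries of 0 h also correlated at 0.61. The simulated shares may therefore not hold for the real comparison at 0 h. Interactions recovered 11.6% at 12 h and 15.5% at 24 h of genes changed 2-fold, and 81.4% and 89.9% of genes changed 4-fold. A planted list of 30 genes changed 1.5-fold was called in each simulated comparison, and 0 of 25 random lists were. Simulated genes varied independently of each other, so these lists do not show how often camera falsely calls lists whose genes vary together. The recovery of reads was checked on simulated libraries, where 2484 of 2486 genes had all reads exact. Other tools were Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Coordinates of genes discussed in the report, in GRCm38, are Ikzf1 on chromosome 11 from 11685003 to 11772926, Il2 on chromosome 3 from 37120523 to 37125959, Ifng on chromosome 10 from 118441046 to 118445892, Il3 on chromosome 11 from 54265303 to 54267277, and Cd163l1 on chromosome 7 from 140218267 to 140231145. Raw reads were not analysed here.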

Results

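Naive CD8 T cells from wild-type (WT) mice and from mice homozygous for the Ikaros-Zn4 mutation (Zn4) were compared at rest and after 12 h and 24 h of stimulation through CD3 and CD28, with 2 libraries per group. Ikzf1, the gene that encodes Ikaros and that carries the mutation, was abundant in all 12 libraries, with group means from 103 ± 16.9 RPKM (SD, n = 2, WT at 0 h) to 138 ± 2.26 RPKM (Zn4 at 24 h). A value per gene cannot show the altered part of the transcript, so Ikzf1 does not check which genotype a library holds. Libraries of the same group correlated at r = 0.980 to 0.995. The SD of the log2 difference between replicates was highest in resting WT cells (0.346) and resting Zn4 cells (0.324) and lowest in WT cells at 24 h (0.173). All p-values measure spread between these samples, because the labels do not say that replicates are separate animals.

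Transcripts that mark the sex of the cells were uneven at 12 h. The labels give female animals for every library. Yet 4 Y-linked genes summed to 38.9 RPKM in WT 12 h replicate 1, 43.4 RPKM in Zn4 12 h replicate 1 and 21.0 RPKM in Zn4 12 h replicate 2. They reached at most 0.0209 RPKM in the other 9 libraries. Xist, the RNA that silences the second X chromosome in female cells, stood at 0.0023, 0.0258 and 24.3 RPKM in those 3 libraries and at 27.2 to 82.7 RPKM elsewhere. Comparisons that use the libraries of 12 h therefore mix genotype or time with the sex of the cells. The WT libraries of 12 h hold cells of different sex, so they come from different animals. Zn4 12 h replicate 2 held both Y-linked transcripts and Xist, while replicate 1 held almost no Xist. If this Xist comes from female cells, replicate 2 holds cells of an animal that is not in replicate 1. For the libraries of 0 h and 24 h, whether replicates come from different animals stays unknown.

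**Figure D1:**
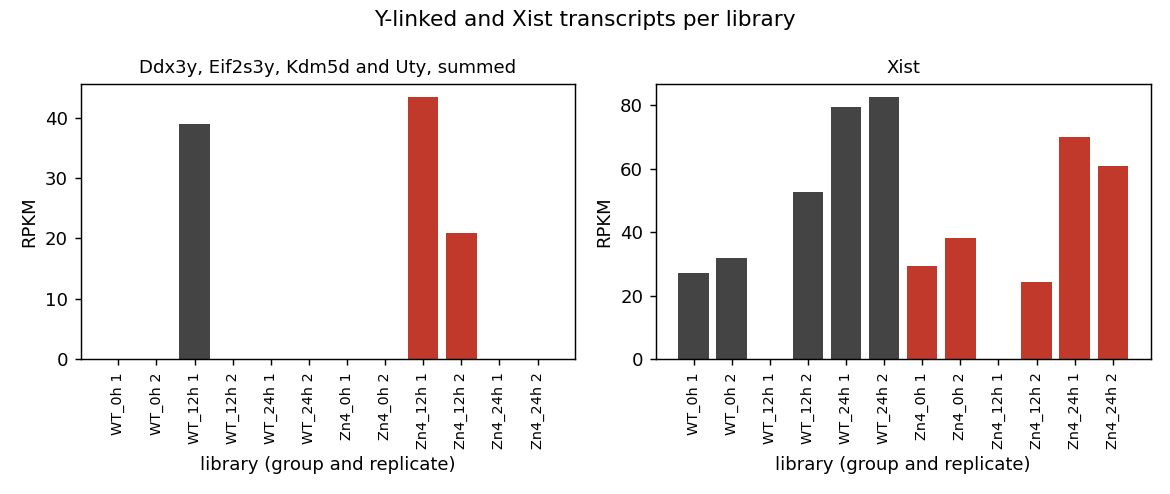
Y-linked transcripts and Xist in the 12 libraries. The summed Y-linked level is 38.9, 43.4 and 21.0 RPKM in 3 libraries of 12 h and at most 0.0209 RPKM in the others.

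Stimulation for 12 h raised genes of growth and some chemokine genes in WT naive cells. Xcl1, which encodes a chemokine of activated CD8 T cells, rose from 0.988 ± 0.292 to 4215 ± 312 RPKM (SD, n = 2 per group, log2 change 11.06 ± 0.18, SE, adjusted p = 2.2e-09). The chemokine genes Ccl4 (log2 change 8.89 ± 0.24) and Ccl3 (7.39 ± 0.38) rose with it. So did the costimulatory receptor Tnfrsf9 (6.67 ± 0.24), the interleukin-2 receptor alpha chain Il2ra (6.11 ± 0.17), the inhibitory receptor Pdcd1 (5.47 ± 0.30) and Tnfsf14 (5.26 ± 0.18). Myc, a driver of cell growth, went from 17.5 ± 10.5 to 263 ± 13.0 RPKM (3.96 ± 0.30), and the effector genes Gzmb (4.72 ± 0.36) and Ifng (3.5 ± 0.20) also rose. Il2 rose by 1.32 ± 0.20 and stayed low, at 1.64 ± 0.792 RPKM. S1pr1, the receptor that lets naive cells leave lymphoid organs, fell from 233 ± 7.75 to 8.0 ± 1.24 RPKM (log2 change -4.71 ± 0.17, adjusted p = 3.1e-08). Il7r (-4.70 ± 0.27), Klf2 (-3.85 ± 0.26), Lef1 (-2.55 ± 0.13) and Tcf7 (-1.87 ± 0.13), which maintain or mark naive cells, fell as well. Further large falls were seen for Vps37b (-5.22 ± 0.29), Cxcr4 (-4.51 ± 0.39), Ifngr1 (-4.50 ± 0.12) and the glucocorticoid target Tsc22d3 (-4.49 ± 0.33).

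Growth programs rose as groups in WT cells by 12 h. All 30 ribosome biogenesis genes were called higher, among them Nop2 (3.15 ± 0.12) and Dkc1 (2.88 ± 0.09), with a median log2 change of 2.07 (adjusted p = 1.2e-10 with a preset correlation between genes, 0.246 with an estimated correlation). Of 23 amino acid and one-carbon genes, 17 rose and 2 fell, with Shmt1 at 3.56 ± 0.17 and Mthfd1 at 3.45 ± 0.13. The list had a median of 1.42 (adjusted p = 0.00128, and 0.246 with an estimated correlation). Sterol and lipid synthesis genes rose in 21 of 25 cases (22 when adjusted over the list alone), including Sqle (2.35 ± 0.11) and Fasn (2.23 ± 0.16), with adjusted p = 0.000851 (0.57 with an estimated correlation). G1/S genes rose in 29 and fell in 2 of 35 cases, with Cdk4 at 3.01 ± 0.09 and Mcm5 at 2.70 ± 0.13. Their median was 1.10 (adjusted p = 0.000851, and 0.672 with an estimated correlation). G2/M genes were split, 5 higher and 5 lower of 30. Glycolysis genes rose in 12 and fell in 1 of 19 cases, led by Tpi1 (3.41 ± 0.17) and Hk2 (3.18 ± 0.14), with adjusted p = 0.00689 (0.246 with an estimated correlation).

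Naive-state genes fell in 24 of 29 cases in WT cells at 12 h, with 3 higher. These genes had a median of -1.96 (adjusted p = 9.6e-08, and 0.103 with an estimated correlation). Interferon-stimulated genes fell in 24 and rose in 3 of 35 cases, with Irf7 at -3.54 ± 0.16 and Ddx58 at -2.54 ± 0.14, against a rise of Gbp2 (2.32 ± 0.25). The list median was -1.08 (adjusted p = 2.7e-05, and 0.659 with an estimated correlation). Trafficking genes fell in 12 and rose in 5 of 20 cases (median -1.52, adjusted p = 0.0272, and 0.246 with an estimated correlation), a call that ended with median-ratio scaling (0.0907) and quantile normalization (0.0693). Other lists were not called: activation genes (18 higher, 7 lower of 31, 19 and 8 over the list alone, adjusted p = 0.175), cytokines (13 and 3 of 24, 0.133), cytotoxic genes (15 and 6 of 27, 0.27), inhibitory receptors (14 and 7 of 25, 0.311) and STAT5 targets (10 and 6 of 20, 0.981). In all, 8928 of 12726 tested genes changed in WT cells between 0 h and 12 h (5488 higher, 3440 lower), and 4169 of them by at least 2-fold. The median gene lay 0.20 higher on the log2 scale at 12 h and 0.31 higher at 24 h (0.19 and 0.31 in Zn4 cells), so changes from 0 h are to be read against these shifts. Median-ratio scaling moved these medians to -0.04 and 0.01 and gave 4256 higher and 4641 lower genes at 12 h.

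By 24 h, WT cells had raised genes of cell division. Mki67, a marker of dividing cells, rose from 0.285 ± 0.0387 RPKM at 12 h to 56.1 ± 7.95 RPKM at 24 h (SD, n = 2 per group, log2 change 5.47 ± 0.18, SE, adjusted p = 1.5e-06). Ccna2 (4.85 ± 0.20), Aurkb (4.33 ± 0.21), Top2a (4.24 ± 0.19) and the ribonucleotide reductase subunit Rrm2 (5.06 ± 0.30) rose in the same interval. G2/M genes rose in 29 of 30 cases (30 when adjusted over the list alone). Their median log2 change was 2.97 (adjusted p = 2.9e-30, and 0.242 with an estimated correlation). G1/S genes rose in 31 of 35 cases (32 over the list alone). The list had a median of 1.46 (adjusted p = 6e-22, and 0.242 with an estimated correlation). Ribosome biogenesis genes turned down in 16 of 30 cases (22 over the list alone). These genes had a median of -0.35 (adjusted p = 1.8e-10, and 0.242 with an estimated correlation). Xcl1 fell by 1.68 ± 0.18, and Npw (-1.88 ± 0.17), Tef (-1.81 ± 0.14), Klf2 (-1.61 ± 0.26), Ikzf3 (-1.32 ± 0.17) and the nucleolar helicase Ddx21 (-0.50 ± 0.09) also fell. Ccl5 (1.85 ± 0.34) and Il2 (1.5 ± 0.20) rose. Cd74 (2.05 ± 0.29) and Cd79b (1.37 ± 0.17) rose as well, and with them the list of 3 B cell markers (2 higher, 3 over the list alone). Its median was 1.37 (adjusted p = 0.0347, and 0.242 with an estimated correlation). This call ended without Zn4 24 h replicate 1 or 2 (adjusted p = 0.0516 in each case), with a pseudocount of 0.1 (0.0611) and with no filter (0.78, 0.114).

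Between 12 h and 24 h, 3052 genes changed in WT cells (2169 higher, 883 lower), 633 of them by at least 2-fold. Median-ratio scaling gave 1886 higher and 1085 lower, and quantile normalization 1566 and 1503. The count at the deposited scaling was 1499 without WT 12 h replicate 1, 1572 without WT 24 h replicate 1 and 1347 without WT 24 h replicate 2, and 1715 with the Y transcript level as a covariate. Against resting cells, 9409 genes differed at 24 h (6153 higher, 3256 lower, 4761 and 4581 with median-ratio scaling), 4751 of them by at least 2-fold. Xcl1 (9.38 ± 0.18, adjusted p = 2.9e-09) and Nrn1 (7.17 ± 0.34) were among the largest rises. Il2ra (6.19 ± 0.17), the DNA methylation cofactor Uhrf1 (5.74 ± 0.21), Gzmb (5.66 ± 0.36), Rrm2 (5.64 ± 0.30), Lag3 (5.53 ± 0.17) and Il2 (2.82 ± 0.20) were also raised. S1pr1 (-5.89 ± 0.17), Klf2 (-5.46 ± 0.26) and the gut-homing receptor Ccr9 (-4.51 ± 0.17) were lower. All 35 G1/S genes were higher at 24 h than at rest (median 3.02, adjusted p = 5e-09, and 0.391 with an estimated correlation), and 23 of 29 naive-state genes were lower. Their median log2 change was -2.04 (adjusted p = 1.1e-08, and 0.077 with an estimated correlation).

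Zn4 cells made most of the same switches. Xcl1 rose from 0.974 ± 0.275 to 9818 ± 204 RPKM by 12 h (SD, n = 2 per group, log2 change 12.29 ± 0.18, SE, adjusted p = 8.5e-10). Ifng (8.35 ± 0.20), Il3 (7.37 ± 0.20), the transcription factor Zbtb32 (7.08 ± 0.21), Gzmb (6.47 ± 0.36) and Il2 (5.02 ± 0.20) rose steeply. S1pr1 (-5.34 ± 0.17), Cd7 (-4.68 ± 0.22) and Cd163l1 (-4.60 ± 0.15) fell. At 24 h against 0 h, Gzmb (8.94 ± 0.36, adjusted p = 4.5e-08), Il3 (7.99 ± 0.20) and Ifng (7.46 ± 0.20) were among the largest rises. Cytokine genes as a list rose in Zn4 cells at 12 h (16 higher, 4 lower of 24, median 2.18, adjusted p = 0.0159, 0.544 with an estimated correlation and 0.0589 in a fit to recovered reads) and at 24 h (20 and 3). The list had a median of 3.49 (adjusted p = 0.00136, and 0.338 with an estimated correlation). Interferon-stimulated genes fell in 32 and rose in 2 of 35 cases at 12 h (33 and 2 over the list alone, median -1.59, adjusted p = 3.5e-09, and 0.44 with an estimated correlation), and naive-state genes fell in 25 and rose in 4 of 29. These genes had a median of -2.25 (adjusted p = 5.9e-08, and 0.102 with an estimated correlation).

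From 12 h to 24 h in Zn4 cells, Mki67 rose by 5.38 ± 0.18, Lmna by 4.62 ± 0.48, Vim by 4.54 ± 0.25, Lgals1 by 4.19 ± 0.16, Csf2 by 3.67 ± 0.28 and Lif by 2.31 ± 0.24. Ccl1 (-2.93 ± 0.42), Xcl1 (-2.64 ± 0.18), Cd160 (-1.91 ± 0.17) and Fbl (-0.79 ± 0.12) fell. All 30 G2/M genes rose (median 3.16, adjusted p = 1.4e-25, and 0.314 with an estimated correlation). Of 20 STAT5 targets 14 rose and 1 fell (median 0.75, adjusted p = 0.000304, and 0.314 with an estimated correlation), and 27 of 30 ribosome biogenesis genes fell. Their median log2 change was -0.49 (adjusted p = 4.1e-14, and 0.314 with an estimated correlation). The Y-linked genes Ddx3y (-3.92 ± 0.99, adjusted p = 0.0137) and Eif2s3y (-3.79 ± 1.01, adjusted p = 0.0175) also fell, which goes with the Y-linked transcripts of the 12 h libraries. These calls ended without Zn4 12 h replicate 1 (adjusted p = 0.0953 and 0.113). They also ended without either Zn4 24 h library (0.062 and 0.0736 without replicate 1, 0.0563 and 0.0669 without replicate 2). Counts in Zn4 were 9296 at 12 h (5533 higher, 3763 lower, 4369 and 4897 with median-ratio scaling) and 9509 at 24 h (6194 and 3315, 4732 and 4715). Between 12 h and 24 h the count was 4273 (2875 and 1398, 2485 and 1725, but 2007 and 2379 with quantile normalization). At least 2-fold changes made up 4815, 4864 and 1073 of these. The last count was 2424 without Zn4 12 h replicate 1 and 1461 with the Y transcript level as a covariate.

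Most stimulation responses were shared by the genotypes. Of the genes called at 12 h against 0 h in both, 4901 were higher in both (2386 for independent lists) and 3044 lower in both (1017), with 55 of 8000 in opposite directions. The values at 24 h against 0 h were 5475 higher (2995 for independent lists), 2689 lower (848) and 78 of 8242 opposite, and from 12 h to 24 h 1726 (490), 578 (97) and 13 of 2317.

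**Figure D2:**
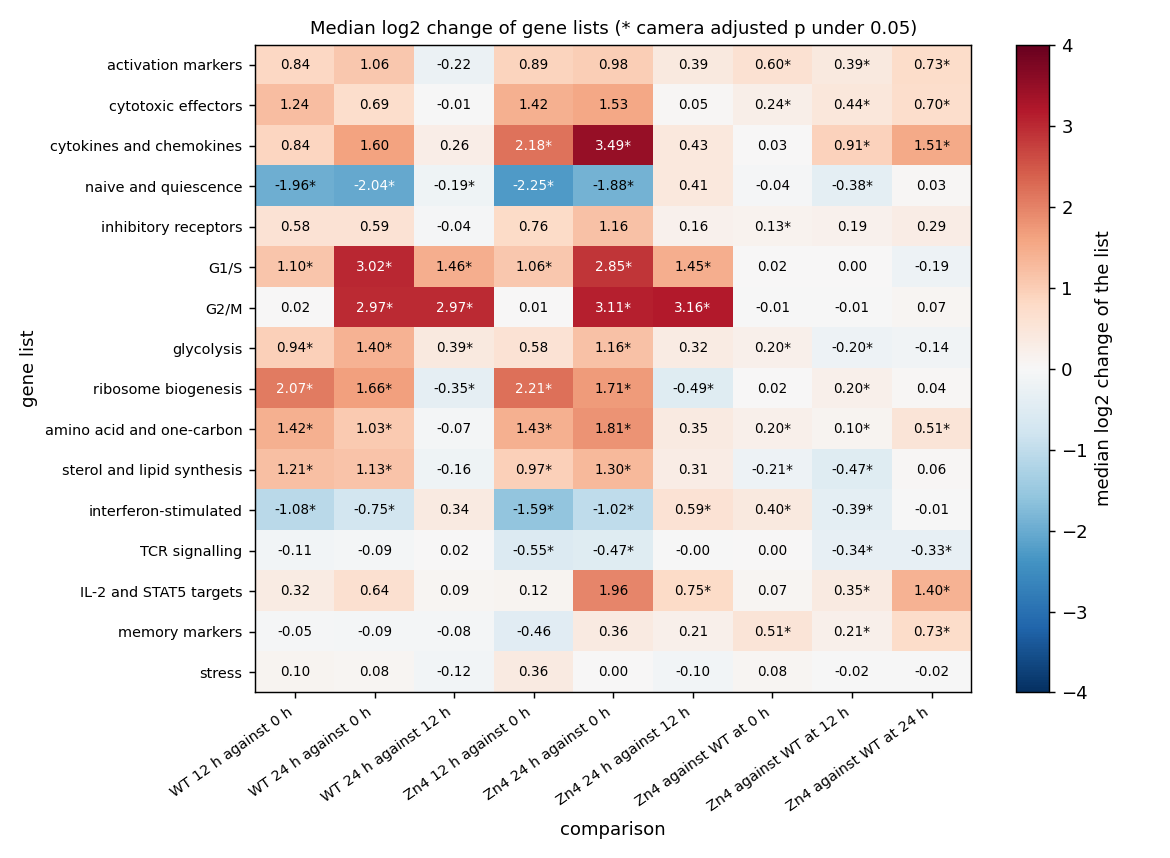
Median log2 change of each gene list in the comparisons. Cytokine genes have a median of 1.51 and STAT5 targets of 1.40 in Zn4 against WT at 24 h.

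At rest, Ikzf1 itself was 0.38 ± 0.10 higher on the log2 scale in Zn4 cells than in WT cells and was not called (adjusted p = 0.0764). With a replicate block at each time point, Ikzf1 was called (adjusted p = 0.035). Without WT 0 h replicate 2 it was 0.54 higher and called (adjusted p = 0.00971). Cd163l1, a scavenger receptor gene, stood at 34.1 ± 0.695 RPKM in Zn4 cells against 0.473 ± 0.0992 RPKM in WT cells (SD, n = 2 per group, log2 difference 4.58 ± 0.15, SE, adjusted p = 7.5e-07). Tmem176b (4.41 ± 0.17), Tmem176a (4.27 ± 0.14), the granzyme gene Gzmm (4.09 ± 0.26) and Nrp1 (3.91 ± 0.19) were higher in both Zn4 libraries than in either WT library. So were Pcsk1 (3.89 ± 0.36), the class II invariant chain gene Cd74 (3.77 ± 0.29) and Tnfsf11 (3.43 ± 0.26), which encodes RANKL. Cxcr3 (2.93 ± 0.24, adjusted p = 0.00012) and Il18r1 (2.30 ± 0.19), receptors of effector and memory T cells, and Kit (1.40 ± 0.17) were also higher. Fam46a (-2.33 ± 0.28), H2-Ob (-2.17 ± 0.18), Gpr174 (-2.10 ± 0.09), Lcn4 (-1.99 ± 0.28), Crlf3 (-1.87 ± 0.18) and Tnfrsf25 (-1.83 ± 0.25) were lower. Cd44, Cd8a and Il7r were not called: Cd44 differed by -0.40 (adjusted p = 0.342), Cd8a by -0.03 (0.953) and Il7r by -0.32 (0.618). The block at each time point called Il7r (adjusted p = 0.0351). Of other Ikaros family genes, those called higher in Zn4 cells were Ikzf2 at 1.43 ± 0.28, Ikzf3 at 1.13 ± 0.17 (adjusted p = 0.00465) and Ikzf4 at 1.02 ± 0.14. The Ikzf2 call (adjusted p = 0.0155) ended without WT 0 h replicate 1 (1.09, adjusted p = 0.0775) and without Zn4 0 h replicate 2 (1.22, 0.105).

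Several activation and memory genes were already raised in resting Zn4 cells. Activation genes as a list were higher in 7 of 31 cases (14 when adjusted over the list alone, median 0.60, adjusted p = 2.1e-06, and 0.141 with an estimated correlation). Called members included Nr4a1 (1.18 ± 0.20), the transferrin receptor Tfrc (0.99 ± 0.17) and Cd69 (0.74 ± 0.14). Memory genes were higher in 5 of 15 cases (9 higher, 2 lower over the list alone). The list had a median of 0.51 (adjusted p = 3.5e-05, and 0.141 with an estimated correlation). The effector regulators Eomes (1.77 ± 0.36, adjusted p = 0.0189) and Tbx21 (1.81 ± 0.37, 0.0194) were higher. Both calls ended without WT 0 h replicate 2 (adjusted p = 0.0978 and 0.1) or without Zn4 0 h replicate 1 (0.107 and 0.08). Without Zn4 0 h replicate 2, the calls ended for Nr4a1 (adjusted p = 0.0534), Tfrc (0.0513), Cd69 (0.101) and the sterol regulator Insig1 (-0.93 ± 0.17, from 0.0124 to 0.0837). Cytotoxic genes were higher in 6 of 27 cases (median 0.24, adjusted p = 0.00138, and 0.503 with an estimated correlation). This call ended without WT 0 h replicate 2 (median 0.08, 0.0964) and without Zn4 0 h replicate 1 (median 0.17, 0.0501). Inhibitory receptors were higher in 6 and lower in 2 of 25 cases (9 and 2 over the list alone, median 0.13, adjusted p = 0.00837, and 0.148 with an estimated correlation). Lag3 (1.08 ± 0.17) was among those higher. Without WT 0 h replicate 2 the list was not called (0.0844).

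Interferon-stimulated genes were higher in 6 and lower in 1 of 35 cases in resting Zn4 cells (14 and 1 over the list alone, median 0.40, adjusted p = 2.3e-05, and 0.503 with an estimated correlation). Oas2 (1.37 ± 0.20) and Oas1a (1.31 ± 0.16) were higher and Oasl1 (-1.12 ± 0.13) lower. Without Zn4 0 h replicate 1 the median was 0.17 and not called (adjusted p = 0.167). Metabolic lists shifted little: glycolysis genes had 2 higher of 19, among them Hk2 (1.29 ± 0.14), with a median of 0.20 (adjusted p = 0.00138, and 0.148 with an estimated correlation). Amino acid and one-carbon genes had 4 higher of 23 (5 higher and 1 lower over the list alone, median 0.20, adjusted p = 0.00178, and 0.228 with an estimated correlation), not called without WT 0 h replicate 1 (median 0.15, 0.0526). Sterol genes were lower in 4 of 25 cases (2 higher, 7 lower over the list alone). These genes had a median of -0.21 (adjusted p = 0.00837, and 0.587 with an estimated correlation). Genes of other T cell lineages had 1 higher of 8 (2 over the list alone, median 0.33, adjusted p = 0.00557, and 0.141 with an estimated correlation), and no G1/S, G2/M or ribosome biogenesis gene was called at rest. In total, 728 genes differed at rest (479 higher, 249 lower), 250 by at least 2-fold. With a replicate block at each time point the count was 1343. Without Zn4 0 h replicate 2 the count was 437, and a fit of the 4 libraries of 0 h alone called 112. That smaller fit did not call Ikzf2 (adjusted p = 0.181), Ikzf3 (0.106), Ikzf4 (0.0962), Pcsk1 (0.0723), Kit (0.0573), Crlf3 (0.0717), Lcn4 (0.158), Eomes (0.152), Tbx21 (0.256), Nr4a1 (0.0909), Tfrc (0.175), Cd69 (0.271), Oas2 (0.158), Oas1a (0.136), Oasl1 (0.11), Hk2 (0.0607) or Insig1 (0.233).

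**Figure D3:**
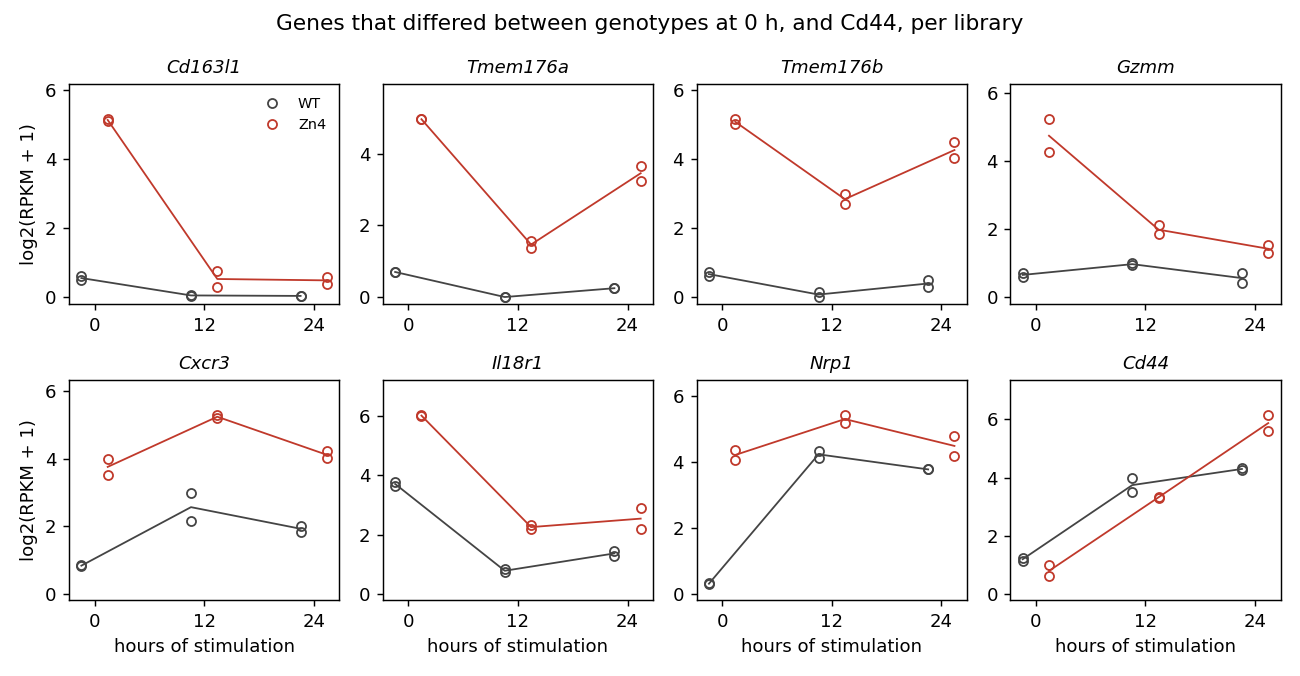
Genes that differed between resting Zn4 and WT cells, and Cd44, in each library. Cd163l1 averaged 34.1 RPKM in resting Zn4 cells and 0.473 RPKM in resting WT cells.

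At 12 h, Ikzf1 was not called between the genotypes (log2 difference -0.09 ± 0.10, SE, adjusted p = 0.681), nor were Ikzf2 (0.63, 0.192) and Ikzf3 (0.56, 0.0649). The replicate block at each time point called Ikzf3 (adjusted p = 0.0238). Ikzf2 was called in the fit of the libraries of 12 h alone (adjusted p = 0.0207), and Ikzf3 without either WT 0 h library (0.0343) and in the fit to recovered reads (0.0394). Il3, a cytokine gene close to silent in WT cells (0.232 ± 0.143 RPKM), reached 174 ± 54.9 RPKM in Zn4 cells (SD, n = 2 per group, log2 difference 7.11 ± 0.20, adjusted p = 3.5e-07). Ifng stood at 472 ± 138 RPKM in Zn4 cells against 11.5 ± 2.59 RPKM in WT cells (5.22 ± 0.20, adjusted p = 1.1e-06). Il2 was at 33.1 ± 3.92 against 1.64 ± 0.792 RPKM (3.72 ± 0.20, adjusted p = 1.3e-05). Ccl1 (6.44 ± 0.42), Pcsk1 (4.20 ± 0.36), the receptor kinase Axl (3.77 ± 0.13), the RNA sensor Ifih1 (3.70 ± 0.25) and the growth factor Hbegf (3.61 ± 0.13) were higher. Smaller rises were those of Cish (2.14 ± 0.17), Eomes (2.03 ± 0.36), Asns (1.84 ± 0.17), Cd74 (1.73 ± 0.29) and Lta (1.57 ± 0.13). Gzmb was 1.82 ± 0.36 higher (adjusted p = 0.00985), a call that ended without WT 12 h replicate 2 (1.27, adjusted p = 0.0699), Zn4 12 h replicate 1 (0.0595) or Zn4 12 h replicate 2 (0.0567). Folr4 (-2.45 ± 0.28), Ephx1 (-2.42 ± 0.28), the actin-binding genes Cotl1 (-2.33 ± 0.16) and Cnn2 (-2.05 ± 0.14), Cd52 (-2.16 ± 0.20), Samhd1 (-2.10 ± 0.15) and the interferon-induced GTPase Gbp2 (-1.95 ± 0.25) were lower. Il2ra, part of the high-affinity receptor for interleukin-2, was 0.54 ± 0.17 higher and not called (adjusted p = 0.0735). With a replicate block at each time point, Il2ra was called (adjusted p = 0.0215). It was called without either Zn4 0 h library (adjusted p = 0.0169), in the fit of the libraries of 12 h alone (0.0114) and in the fit to recovered reads (0.0411).

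Cytokine genes as a list were higher in 13 and lower in 2 of 24 cases at 12 h (median 0.91, adjusted p = 2.3e-08, and 0.231 with an estimated correlation). Cytotoxic genes were higher in 9 and lower in 1 of 27 cases (10 and 2 over the list alone). Their median log2 change was 0.44 (adjusted p = 0.000188, and 0.373 with an estimated correlation). STAT5 targets, downstream of interleukin-2, were higher in 7 and lower in 1 of 20 cases (8 and 2 over the list alone). The list had a median of 0.35 (adjusted p = 6.6e-05, and 0.231 with an estimated correlation). Genes of T cell receptor signalling were lower in 13 and higher in 1 of 30 cases (16 and 2 over the list alone, median -0.34, adjusted p = 0.0001, and 0.231 with an estimated correlation). Prkcq (-1.07 ± 0.13) and Cd3g (-1.07 ± 0.15) were lower, and Cd247 (1.08 ± 0.15) was higher. Sterol genes were lower in 9 of 25 cases (18 over the list alone, median -0.47, adjusted p = 1.9e-07, and 0.231 with an estimated correlation), including Dhcr7 (-1.26 ± 0.14). Interferon-stimulated genes were lower in 13 and higher in 1 of 35 cases, Ifih1 being the higher one (16 and 2 over the list alone, median -0.39, adjusted p = 0.00147, and 0.549 with an estimated correlation). Naive-state genes were lower in 8 and higher in 1 of 29 cases (13 and 2 over the list alone). These genes had a median of -0.38 (adjusted p = 0.0011, and 0.231 with an estimated correlation). Memory genes were higher in 6 and lower in 1 of 15 cases (median 0.21, adjusted p = 0.00631, and 0.231 with an estimated correlation). Amino acid genes were higher in 4 of 23 cases (median 0.10, adjusted p = 0.00643, and 0.278 with an estimated correlation) and ribosome biogenesis genes in 3 of 30 (1 over the list alone, median 0.20, 6.8e-06, and 0.278 with an estimated correlation).

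Glycolysis genes were lower in 6 and higher in 1 of 19 cases (7 and 1 over the list alone), Pfkm among them (-1.13 ± 0.16), with a list median of -0.20 (adjusted p = 0.0196, and 0.278 with an estimated correlation). Without WT 12 h replicate 1 the list was not called (-0.19, adjusted p = 0.0541). Activation genes were 3 higher and 3 lower of 31 (6 and 5 over the list alone, median 0.39, adjusted p = 0.0477, and 0.44 with an estimated correlation). This call ended with median-ratio scaling (0.0694), quantile normalization (0.166), without WT 12 h replicate 1 (0.163), without Zn4 12 h replicate 2 (0.0795) and without either Zn4 24 h library (0.0623). Altogether 1671 genes differed at 12 h (617 higher, 1054 lower), 475 by at least 2-fold. The count was 1047 and 769 without WT 12 h replicate 1 or 2, and 743 and 1105 without Zn4 12 h replicate 1 or 2. Because both Zn4 libraries and 1 WT library of 12 h hold Y-linked transcripts, sex and genotype are partly mixed here; with the Y transcript level as a covariate, 1117 of the 1671 genes were called in the same direction.

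At 24 h, Ikzf1 was 0.25 ± 0.10 higher in Zn4 cells and not called (adjusted p = 0.136, called without either WT 0 h library, 0.0347). Il3 stood at 262 ± 30.9 RPKM in Zn4 cells against 0.978 ± 0.193 RPKM in WT cells (SD, n = 2 per group, log2 difference 7.05 ± 0.20, SE, adjusted p = 3.8e-07). Il2 was at 102 ± 19.5 against 6.30 ± 0.344 RPKM (3.81 ± 0.20) and Ifng at 251 ± 38.2 against 18.6 ± 0.167 RPKM (3.67 ± 0.20). Csf2, the gene for GM-CSF, was at 70.3 ± 16.5 against 1.26 ± 0.0375 RPKM (4.96 ± 0.28). Gzmb, a granzyme of killer cells, was at 1198 ± 513 against 111 ± 3.14 RPKM (3.35 ± 0.36, adjusted p = 0.000328). Gzmc (4.42 ± 0.53), Tnfsf11 (4.27 ± 0.26), Eomes (3.10 ± 0.36) and Lif (2.33 ± 0.24) were higher. Cd44, which marks activated cells, was at 58.5 ± 15.1 against 18.7 ± 0.69 RPKM (1.57 ± 0.20). Other large differences were the rises of Lmna (4.68 ± 0.48), Plaur (4.49 ± 0.41), Ier3 (4.40 ± 0.32), Ifitm3 (4.38 ± 0.20), Gadd45b (3.95 ± 0.36), Atf3 (3.43 ± 0.59), Batf3 (3.39 ± 0.25) and Bhlhe40 (2.63 ± 0.37). Ephx1 (-2.72 ± 0.28), Pyhin1 (-2.61 ± 0.18), Folr4 (-2.41 ± 0.28) and Itm2a (-2.30 ± 0.19) were lower. Prf1 (0.27, adjusted p = 0.633) and Tbx21 (-0.15, 0.824) were not called.

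Among Ikaros family genes at 24 h, Ikzf2 was 1.08 ± 0.28 higher (adjusted p = 0.0246), Ikzf3 0.70 ± 0.17 higher (0.02) and Ikzf4 1.02 ± 0.14 higher. Ikaros and NuRD complex genes had 4 higher, all of the Ikaros family, and 3 lower of 25 (median -0.05, adjusted p = 0.852). The Ikzf2 call ended without Zn4 24 h replicate 1 (0.68, adjusted p = 0.184), WT 24 h replicate 1 (0.136) or WT 24 h replicate 2 (0.0948), and in the fit of the libraries of 24 h alone (0.0706). Leaving out WT 24 h replicate 1 (adjusted p = 0.0691), WT 24 h replicate 2 (0.133) or Zn4 24 h replicate 2 (0.0977) ended the Ikzf3 call. Il2ra was 0.84 ± 0.17 higher (adjusted p = 0.00855), and this call ended without WT 24 h replicate 1 (0.0615), WT 24 h replicate 2 (0.0525) or Zn4 24 h replicate 1 (0.0794) and with a pseudocount of 0.1 (0.107).

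STAT5 targets had the lowest p among the lists at 24 h, with 15 higher and 1 lower of 20 (16 and 2 over the list alone, median 1.40, adjusted p = 3.4e-10, and 0.164 with an estimated correlation). Cish (2.50 ± 0.17) and Pim1 (2.08 ± 0.21) were among those higher. The STAT5 list shares members with the cytokine, activation, cytotoxic and inhibitory receptor lists, so it is not a separate result. Cytokine genes were higher in 14 and lower in 2 of 24 cases (median 1.51, adjusted p = 6.3e-09, and 0.188 with an estimated correlation). Cytotoxic genes were higher in 14 and lower in 1 of 27 cases (14 and 2 over the list alone, median 0.70, adjusted p = 9.5e-07, and 0.237 with an estimated correlation). Activation genes were higher in 16 and lower in 1 of 31 cases (18 and 1 over the list alone, median 0.73, adjusted p = 2.35e-05, and 0.188 with an estimated correlation). Memory genes were higher in 8 and lower in 1 of 15 cases. Their median log2 change was 0.73 (adjusted p = 0.000413, and 0.188 with an estimated correlation). Amino acid and one-carbon genes were higher in 11 and lower in 1 of 23 cases (12 and 2 over the list alone, median 0.51, adjusted p = 0.000413, and 0.231 with an estimated correlation). Trib3 (2.37 ± 0.34), Chac1 (2.16 ± 0.27) and Asns (2.08 ± 0.17), genes of the amino acid response, were all higher. T cell receptor signalling genes were lower in 13 and higher in 1 of 30 cases (15 and 1 over the list alone, median -0.33, adjusted p = 0.00144, and 0.237 with an estimated correlation). Prkcq (-1.23 ± 0.13), Cd3g (-1.18 ± 0.15) and Cd3e (-0.97 ± 0.12) were lower, and Cd247 (1.34 ± 0.15) was again higher. Cell cycle lists did not part the genotypes: G1/S genes had 2 higher and 2 lower of 35 (adjusted p = 0.0962) and G2/M genes 1 higher of 30 (0.312). Sterol (adjusted p = 0.96), naive-state (0.852), interferon (0.737) and glycolysis genes (0.171) were not called either. A total of 2464 genes differed (1196 higher, 1268 lower), 649 by at least 2-fold. This count fell when any other library of 24 h was left out, but not without Zn4 24 h replicate 2. The count was 1061 and 1075 without WT 24 h replicate 1 or 2, and 1234 without Zn4 24 h replicate 1.

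**Figure D4:**
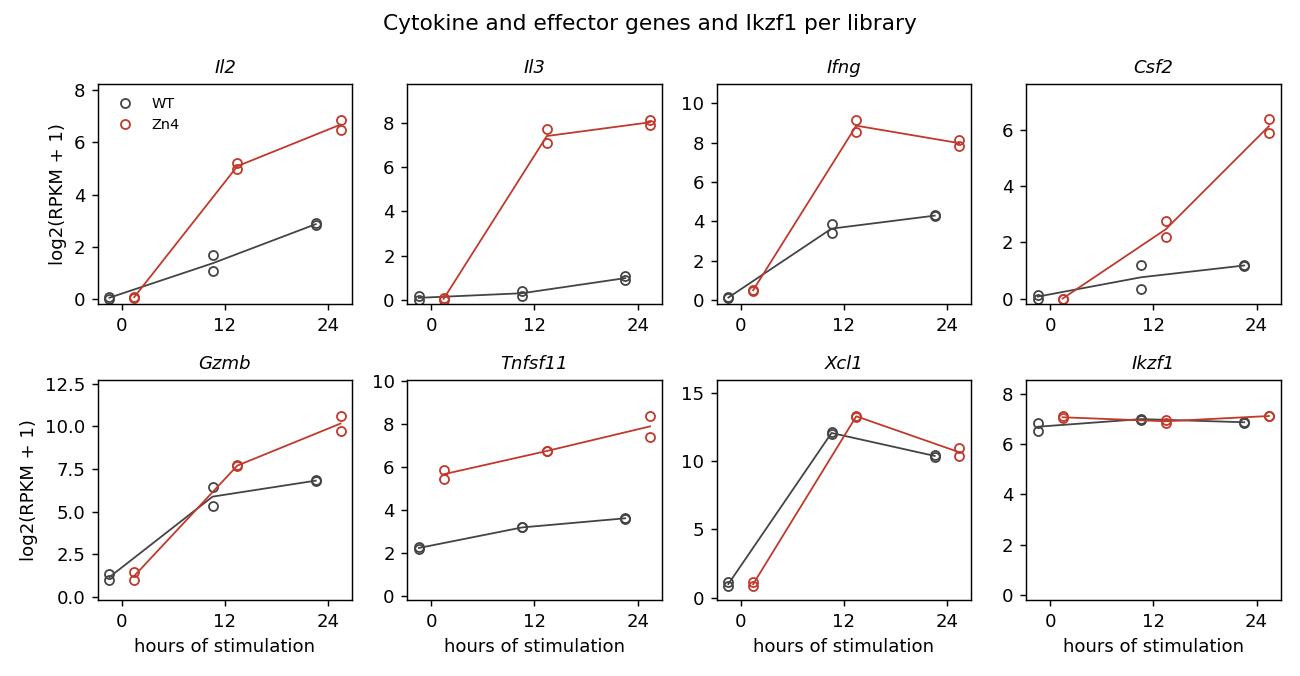
Cytokine and effector genes and Ikzf1 in each library. Il2 averaged 102 RPKM in Zn4 cells and 6.30 RPKM in WT cells at 24 h.

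Genotype differences at 12 h and 24 h shared many genes: 432 were higher at both times (58 for independent lists) and 646 lower at both (105), with 14 of 1092 in opposite directions. Between 0 h and 12 h the shared genes were 165 higher (23) and 101 lower (21), with 24 of 290 opposite, and between 0 h and 24 h 231 higher (45) and 97 lower (25), with 30 of 358 opposite.

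The difference in response between the genotypes was tested for each gene. For Il3 the 12 h response exceeded that of WT cells by 7.16 ± 0.28 on the log2 scale (SE, n = 2 libraries in each of 4 groups, adjusted p = 8e-06). The rise was also larger for Ccl1 (6.43 ± 0.59), Ifng (4.85 ± 0.28), Il2 (3.70 ± 0.28) and Hbegf (3.54 ± 0.18). Cd247 fell in WT cells and was not called in Zn4 cells (difference in response 1.54 ± 0.21). At 24 h the difference in response was 7.10 ± 0.28 for Il3, 5.03 ± 0.40 for Csf2, 4.31 ± 0.75 for Gzmc and 3.79 ± 0.28 for Il2. It was 3.30 ± 0.28 for Ifng, 3.28 ± 0.51 for Gzmb and 1.97 ± 0.28 for Cd44. It was also positive for Plaur (5.22 ± 0.58), Pim1 (2.17 ± 0.30) and Cd247 (1.79 ± 0.21), which fell in WT cells by 24 h and were not called in Zn4 cells. Of the genes raised in resting Zn4 cells, Cd163l1 (-4.10 ± 0.21 at 12 h, -4.13 ± 0.21 at 24 h), Gzmm (-3.08 ± 0.37 and -3.23 ± 0.37) and, at 24 h, Cd74 (-3.21 ± 0.40) had a lower response. The test subtracts the difference at rest, so for these genes it partly restates that difference. Cd163l1 lay below 1 RPKM in resting WT cells and could hardly fall there. For Il3, Ccl1, Il2, Hbegf, Csf2, Gzmc and Gzmb the genotypes hardly differed at rest on this scale. The added 1 RPKM damps any resting difference between levels near 0. Their differences in response therefore largely restate the genotype difference at 12 h or 24 h and are not separate results. Gbp2 (-3.04 ± 0.35 at 12 h, -2.65 ± 0.35 at 24 h) and, at 12 h, Cd3d (-1.02 ± 0.15) had a lower response in Zn4 cells. A fit to whole reads recovered from the RPKM values did not call the 12 h difference for Ccl1 (7.60, adjusted p = 0.253), Ifng (3.45, 0.113), Il2 (3.64, 0.159) or Cd163l1 (-2.90, 0.0726). At 24 h it did not call Gzmc (4.54, 0.428), Il2 (3.30, 0.163), Ifng (1.83, 0.367), Gzmb (3.26, 0.106) or Cd163l1 (-2.54, 0.111).

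Cytokine genes showed a larger response in Zn4 cells at 12 h (9 higher of 24, 9 higher and 2 lower over the list alone, median 0.38, adjusted p = 5.7e-07, and 0.213 with an estimated correlation). In the fit to recovered reads this median was 0.21 and not called (adjusted p = 0.0797). At 24 h the response was larger for 10 and smaller for 1 (12 and 1 over the list alone, median 0.80, adjusted p = 1.2e-07, and 0.178 with an estimated correlation). STAT5 targets did so at 24 h (9 higher of 20, 11 higher and 1 lower over the list alone). The list had a median of 1.07 (adjusted p = 5.8e-08, and 0.178 with an estimated correlation). Interferon-stimulated genes responded with a deeper fall at 12 h (11 lower, 2 higher of 35, 18 and 2 over the list alone, median -0.78, adjusted p = 7.1e-08, and 0.397 with an estimated correlation). T cell receptor signalling genes (11 lower, 2 higher of 30, 15 and 3 over the list alone, median -0.46, adjusted p = 7e-05, and 0.213 with an estimated correlation) also had a lower response in Zn4 cells. So had glycolysis genes, with 4 lower of 19 (8 over the list alone) and a median of -0.44 (adjusted p = 8.7e-07, and 0.161 with an estimated correlation). The interferon and glycolysis lists were higher in resting Zn4 cells, so their lower response partly restates that difference. The responses of 651 genes differed at 12 h (196 higher, 455 lower, 339 by at least 2-fold) and of 1048 genes at 24 h (494 higher, 554 lower, 488 by at least 2-fold). Leaving out Zn4 24 h replicate 2 did not lower the 24 h count. The 12 h count was 252 without WT 12 h replicate 2, 236 without Zn4 12 h replicate 1, 399 without Zn4 0 h replicate 2 and 372 without either WT 24 h library. The 24 h count was 340 and 325 without WT 24 h replicate 1 or 2, 677 without Zn4 0 h replicate 2 and 566 without Zn4 24 h replicate 1.

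Genes that WT cells repress by 24 h were slightly lower still in Zn4 cells at 12 h: of 1417 such genes, 216 were lower and 46 higher (median -0.14, camera p = 5.5e-05, and 0.138 with an estimated correlation). The 3334 genes induced by 24 h in WT cells had 192 higher and 188 lower (median 0.02, camera p = 0.0369, and 0.553 with an estimated correlation). This call ended without WT 12 h replicate 2 (0.113) or Zn4 12 h replicate 2 (0.203). The 2668 genes that WT cells induce by 12 h, with 229 higher and 231 lower, were not called as a class at 24 h (median -0.05, camera p = 0.427 with a preset correlation). They were called without Zn4 24 h replicate 2 (median -0.11, p = 0.0123 with a preset correlation). The 1501 genes repressed by 12 h, with 182 higher and 227 lower, were not called either (median -0.04, camera p = 0.585 with a preset correlation), except without Zn4 24 h replicate 1 (median -0.08, p = 0.0493). These p-values are not adjusted over the 4 classes.

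Ikaros and NuRD complex genes had 3 higher and 1 lower of 25 at rest (4 and 1 over the list alone, adjusted p = 0.186). Notch targets had 1 higher of 6 (2 over the list alone, 0.466), trafficking genes 4 higher and 1 lower of 20 (4 and 3 over the list alone, 0.224), survival and p53 genes 1 higher and 1 lower of 22 (1 higher and 2 lower over the list alone), and stress genes none of 24 (3 over the list alone, 0.195). At 24 h, stress genes had 6 higher in Zn4 cells, with Gadd45b and Atf3 among them, and 2 lower, both mitochondrial (adjusted p = 0.529). Survival and p53 genes had 7 higher and 3 lower of 22 (7 and 4 over the list alone, 0.238) and inhibitory receptors 10 and 5 of 25 (11 and 8 over the list alone, 0.0922). Markers of other cell types were few among the tested genes. There were 3 of B cells (Cd74 higher at rest, list adjusted p = 0.721) and 3 of myeloid cells (Itgam at 0.83 ± 0.09, list median 0.64, adjusted p = 0.00662, and 0.148 with an estimated correlation). There were 4 of natural killer and gamma-delta T cells (none called, 0.933), 2 of progenitors (Kit higher) and 1 of erythroid cells (not called). Cd79b, a B cell receptor gene, was lower in Zn4 cells at 12 h (-1.02 ± 0.17) and 24 h (-1.52 ± 0.17).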

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

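Tests chosen only after the result was seen are those of library scaling and of the other sex for the cytokine genes, those of memory and gamma-delta T cells for the genes of resting cells, and all tests of Y-linked transcripts; the tests that leave out 1 library, where the lone sample left in a group is assumed to vary like the other groups, were chosen before.

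The response to stimulation differed between the genotypes by a test of the difference itself for 651 genes at 12 h and 1048 genes at 24 h. Cytokine genes differed by a list median of 0.38 on the log2 scale at 12 h and 0.80 at 24 h. STAT5 targets differed by 0.31 and 1.07. Genes of T cell receptor signalling differed by -0.46 and -0.43, glycolysis genes by -0.44 and -0.35, and interferon-stimulated genes by -0.78 and -0.43. The lists of naive-state genes (-0.40), ribosome biogenesis (0.17) and sterol synthesis (-0.22) were called at 12 h, and cytotoxic genes (0.45) at 24 h; whether these differences change between 12 h and 24 h was not tested. The 3 myeloid markers differed by -0.87 and -1.12, and the 3 B cell markers, Cd74 among them, by -1.26 at 24 h. Glycolysis (median 0.195), interferon-stimulated (0.395) and myeloid genes (0.64) were higher in resting Zn4 cells. The test subtracts that difference, so their lower response partly restates it. At 24 h itself the glycolysis and interferon lists were not called between the genotypes. Each of the list calls for the difference in response was lost with an estimated correlation. A fit to recovered reads ended the calls of cytokine (0.21, adjusted p = 0.0797), sterol (0.065) and STAT5 genes (0.065) at 12 h and of cytotoxic genes (0.0906) at 24 h. The interferon call at 24 h was also lost without Zn4 0 h replicate 1 (-0.13; adjusted p = 0.296). The 24 h cytotoxic call was lost without WT 0 h replicate 1 (0.208) or Zn4 0 h replicate 2 (0.301). B cell markers lost their call without WT 0 h replicate 2 (0.114), Zn4 0 h replicate 1 (0.0576) or Zn4 24 h replicate 1 (0.0506). At 12 h, the ribosome biogenesis call was lost without WT 12 h replicate 2 (0.0629), the sterol call without WT 12 h replicate 2 (0.129) or Zn4 0 h replicate 1 (0.0694), and the STAT5 call without Zn4 0 h replicate 1 (0.122) or Zn4 12 h replicate 2 (0.0517).

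Single genes whose response at 12 h differed by the same test were Il3 (7.16), Ccl1 (6.43), Ifng (4.85), Il2 (3.70), Hbegf (3.54) and Cd247 (1.54), with a larger rise or smaller fall in Zn4 cells, and Cd163l1 (-4.10), Gzmm (-3.08), Gbp2 (-3.04) and Cd3d (-1.02) the other way. At 24 h they were Il3 (7.10), Plaur (5.22), Csf2 (5.03), Gzmc (4.31), Il2 (3.79), Ifng (3.30), Gzmb (3.28), Pim1 (2.17), Cd44 (1.97) and Cd247 (1.79), against Cd163l1 (-4.13), Gzmm (-3.23), Cd74 (-3.21) and Gbp2 (-2.65). For Il3, Ccl1, Il2, Hbegf, Csf2, Gzmc and Gzmb these values largely restate the genotype difference at the same time. In the fit to recovered reads the calls were lost at 12 h for Ccl1 (adjusted p = 0.253), Ifng (0.113), Il2 (0.159) and Cd163l1 (-2.90, 0.0726). At 24 h they were lost for Gzmc (0.428), Il2 (0.163), Ifng (1.83, 0.367), Gzmb (0.106) and Cd163l1 (-2.54, 0.111).

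The excess of cytokine transcripts in Zn4 cells at 24 h was set against technical explanations. The call of the list was itself lost with an estimated correlation (adjusted p = 0.188). The mean median-ratio factors of the Zn4 and WT libraries of 24 h differed by -0.00734 on the log2 scale, and the list median under that scaling was 1.45, which argues against library scaling. Leaving out each library of 24 h in turn gave a list median of at least 1.31 and adjusted p of at most 8.2e-07, which argues against a single library as the source. Y-linked transcripts reached at most 0.00272 RPKM at 24 h, so male cells cannot account for it. Whether the Ikaros mutation acts on the cytokine genes directly or through the altered state of the resting cells stays open. This design cannot part these routes. Other differences between the animals or cultures of the genotypes, or in their share of cell subsets, were not tested and stay open too.

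The higher level of Gzmm, Cxcr3, Il18r1, Cd163l1 and Tmem176b in resting Zn4 cells was also weighed. Memory cells that escaped the sort for low CD44 would bring Ccl5 and Cd44, but the higher of their 2 log2 changes was 0.032. Cells of both genotypes were sorted for low CD44, so Cd44 decides little here. Eomes (1.77) and Tbx21 (1.81) rose, though their calls ended in some fits without 1 library. The memory list, which holds Gzmm, Cxcr3 and Il18r1, had a median of 0.51 (adjusted p = 0.141 with an estimated correlation). Memory-like cells low in CD44 are therefore not excluded. Gamma-delta T cells would raise the constant-region transcripts of the gamma locus, but their sum was 4.11 RPKM in Zn4 cells against 4.20 RPKM in WT cells (difference -0.0891), while Cd163l1 alone rose by 33.6 RPKM. Leaving out each library of 0 h in turn left the lowest change among the 5 genes at 2.24. An altered program of the naive cells of Zn4 animals may explain the pattern, and a subset of cells without these markers stays open and was not tested. The 3 myeloid markers (list median 0.64, adjusted p = 0.00662, and 0.148 with an estimated correlation, Itgam at 0.83 ± 0.09) and Cd74 (3.77 ± 0.29) were higher in the same comparison, so a share of other cell types is not excluded. The list of B cell markers that holds Cd74 was not called, and Ighm was lower in the resting Zn4 libraries than in the resting WT libraries.

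Y-linked transcripts in 3 libraries of 12 h go against the label of female animals. Xist was at most 0.0258 RPKM in WT 12 h replicate 1 and Zn4 12 h replicate 1, far below the 52.6 RPKM of WT 12 h replicate 2, which argues against reads of another library mixed into female ones and is consistent with male cells. In Zn4 12 h replicate 2 the Y-linked level was 0.483 of that in the highest library, with Xist at 24.3 RPKM, which is consistent with a mix of male and female cells. Of the 1671 genes called between genotypes at 12 h, 1117 were called in the same direction with the Y transcript level as a covariate, which argues against sex as the source of all these calls, though not of each. No biological explanation was tested.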

How the results depend on the processing

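Alternatives chosen only after results were seen are the fit to recovered reads, the Y transcript level as a covariate and the block at each time point. Where 1 library was left out, the lone sample left in its group is assumed to vary like the other groups.

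Requiring at least 2-fold change left 4169, 4751 and 633 genes in WT (12 h and 24 h against 0 h, 24 h against 12 h), 4815, 4864 and 1073 in Zn4, 250, 475 and 649 between genotypes at 0 h, 12 h and 24 h, and 339 and 488 for the difference in response at 12 h and 24 h. With only the libraries of the comparison, the count rose from 3052 to 5094 for WT 24 h against 12 h and went from 728 to 112 between genotypes at 0 h and from 1048 to 550 for the difference in response at 24 h. The Y covariate lowered the counts between 12 h and 24 h to 1715 in WT and 1461 in Zn4.

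No label pairs the samples by replicate number. Deviations of same-numbered libraries correlated at 0.61 between genotypes at 0 h, 0.19 at 12 h and 0.04 at 24 h. At 0 h libraries of the same number may therefore share a source of variation, which the main fit does not model. A replicate block shared by all groups gave 753, 1716 and 2531 genes between genotypes at 0 h, 12 h and 24 h, and a block at each time point 1343, 2644 and 3794, with 1319 and 2029 for the difference in response. That block at each time point also called Ikzf1 (adjusted p = 0.035) and Il7r (0.0351) at 0 h and Ikzf3 (0.0238) and Il2ra (0.0215) at 12 h, and ended the calls of the cytotoxic (0.0546) and B cell lists (0.0556) for the difference in response at 24 h. The shared block ended those of B cell markers in WT 24 h against 12 h (0.0524) and of trafficking genes in WT 24 h against 0 h (0.0508, and 0.0514 with a block within genotype).

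Leaving out each of the 12 libraries in turn gave 1347 to 3391 genes for WT 24 h against 12 h and 2424 to 4656 for Zn4 24 h against 12 h. It gave 437 to 815, 743 to 1834 and 1061 to 2778 between genotypes at 0 h, 12 h and 24 h, and 236 to 789 and 325 to 1524 for the difference in response at 12 h and 24 h.

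For the classes of genes defined in WT cells, an estimated correlation ended the calls at 12 h for genes induced by 24 h (median 0.0243) and repressed by 24 h (-0.14), and quantile normalization that of the induced genes (0.0315; p = 0.102). When 1 library was left out, the medians of the induced genes ran from -0.0027 to 0.0527. Those of the repressed genes ran from -0.164 to -0.101. At 24 h, those of genes induced by 12 h ran from -0.114 to 0.0203 and those of genes repressed by 12 h from -0.0757 to 0.

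Among 213 results for single genes, leaving out a library ended 28 calls and added 7 with 2521 unchanged, the fit to recovered reads ended 9 and added 2, only the libraries of the comparison ended 18 and added 2, and the other settings changed at most 4. Among 98 called lists, an estimated correlation ended all 98, median-ratio scaling 9, quantile normalization 8, the filter at 5 RPKM 7, recovered reads 6 and other settings at most 3, while leaving out a library ended 25 and left 1151. No result changed direction while called.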

Other observations

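The genes of this part were chosen after their values were seen, and so were the patterns; the tests of the actin filament and hypoxia lists were written before those lists were computed.

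Cotl1, Cnn2 and Actb were lower in Zn4 cells than in WT cells at 12 h; Actb stood at 684 and 756 RPKM in the Zn4 libraries against 1249 and 1430 RPKM in the WT libraries. Actin filament genes as a list of 24 had a median log2 change of -0.42 at 12 h, with 14 lower and none higher (19 lower over the list alone, p = 1.9e-10, and 0.0289 with an estimated correlation). Coro1a was at 63.4 and 86.6 RPKM against 259 and 292 RPKM, and Tmsb4x at 554 and 594 against 991 and 1195 RPKM. The list was also lower at 24 h (median -0.24, 9 lower, 1 higher, p = 0.000719, and 0.18 with an estimated correlation) and slightly so at rest (-0.11, p = 0.0199, and 0.337 with an estimated correlation). These values suggest that actin filament genes may be held lower in stimulated Zn4 cells, a hypothesis found and tested on the same data.

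Ndrg1 and Adm were higher in Zn4 cells at 24 h, with Ndrg1 at 52.7 and 20.3 RPKM against 2.71 and 2.40 RPKM, and Adm at 35.2 and 12.3 against 0.687 and 0.588 RPKM. Hypoxia could raise these genes, but of 18 tested hypoxia-induced genes 2 were higher and 1 lower (median 0.14, p = 0.352, and 0.561 with an estimated correlation), which leaves that explanation undecided. In both genes the level of Zn4 24 h replicate 1 exceeded that of replicate 2.

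Ighm, the immunoglobulin heavy chain gene, was found at 170 and 86.1 RPKM in resting WT libraries and at 70.9 and 55.1 RPKM in resting Zn4 libraries, at 240 to 243 RPKM in WT cells at 24 h and at 97.2 and 161 RPKM in Zn4 cells at 24 h. The rise from 0 h to 24 h was called in both genotypes (0.99 ± 0.30 in each). No test of its source was made.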
